A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

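Affymetrix arrays that carry probe sets of S. cerevisiae and of the fission yeast S. pombe were hybridised with labelled RNA of 6 S. cerevisiae samples. Per the labels, the strains were a wild type of the S288C-derived laboratory background, given as BY4147 in some places and BY4741 in others, and its derivative in which a kan marker replaces PMR1. Per the labels' protocols, cells grew to mid-log phase in rich YPAD medium with 5 mM calcium chloride, total RNA was isolated with a column kit, and 100 ng of it was amplified from the transcript ends and labelled with biotin. The groups were taken from the titles, 3 samples each, and each column of the table was matched to its sample by name. The labels give no hybridisation or scan batch, so none was examined.

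The deposited table holds 10928 probe sets on 6 arrays as log2 values, and per the submitters' processing notes the authors used GCOS, RMA and limma, with no versions given. RMA corrects the background, sets the arrays to a common distribution and summarises probes, and it compresses large folds and folds of dim genes. The table has 0 missing values and 0 columns of other samples. Per the probe annotation, 7245 probe sets are named, 7244 with 1 gene symbol and 1 with several, and 3683 have none. The gene table of assembly R64 served for current names and for which genes adjoin, and updated 12 symbols. The genome build behind the array is not given in the sources used here, and no coordinates are printed. Tested were 5498 S. cerevisiae probe sets for 5449 genes, of which 47 have more than 1 probe set. The 1747 S. pombe, 3470 unnamed and 213 control probe sets were left out of the main test.

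The groups were compared on the deposited log2 values with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with 2 groups and two-sided tests, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets with a threshold of 0.05. Array background was the 95th percentile of the S. pombe probe sets on each array, 4.18 to 4.31 (4.23 for their mean levels over the arrays). A probe set below it on every array of a group has only a bound there, computed from the mean of the other group and, per array, the higher of that background and the probe set's own value. This floor was chosen after the values were seen. For arrays, no depth is given, and the number of arrays limits the precision. The median SE of a log2 change was 0.0477. In data simulated on the same 5498 probe sets, with 50 probe sets changed at each size, limma recovered 62% of log2 changes of 0.25, 92% of 0.5, 94% of 1 and 100% of 2. Only 200 probe sets were changed there, with independent noise, against 1605 past the threshold in the data. These shares are therefore not the recovery in the data.

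The comparison, its test, 35 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The lists covered calcineurin and Crz1 targets, calcium homeostasis, manganese, iron, zinc, copper and phosphate, the unfolded protein response, glycosylation in the ER and the Golgi, the cell wall, vesicle coats, SNAREs with Rabs and tethers, the vacuolar ATPase, autophagy, general and oxidative stress, nitrogen catabolite repression, Gcn4 targets, sulfur metabolism, glycolysis, respiration, the citrate and glyoxylate cycles, ergosterol, inositol and phospholipids, ribosome biogenesis, ribosomal proteins, DNA damage, histones, the G1 and S and the M and M/G1 phases, pheromone response, a-cell-specific, alpha-cell-specific and sporulation genes. Each was tested with limma's camera at a preset correlation of 0.01, with 1 probe set per gene (that with the highest mean), adjusted over the lists, and PMR1 and the background deletions were left out of every list. Camera asks whether a list is shifted against the other genes. Fry's directional test asks whether the genes of a list move, on balance, one way, and compares them with no other genes.

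Named genes were PMR1, its neighbours HUR1 and CUP2, the deleted background markers, the 15 largest rises and 15 largest falls past the threshold whose groups do not overlap, and up to 4 members of each list with the largest change. Members of that last part whose call ended without 1 of the arrays are mostly given within the counts only. SLT2, CWP1, SAM3, ARN2, FRE4, TPS2, NTH1, STE6, ASG7 and BAR1 fall outside the rule and were chosen after their values were seen. The alternatives were an intensity trend with robust priors, renewed quantile, median and cyclic loess scaling, a filter on dim probe sets, all probe sets of the array, no probe sets that can bind several transcripts, array weights, a replicate block, leaving out each array in turn, camera with an estimated correlation, fry, and the mean over the probe sets of a gene. Added after the data were seen were the background floor and 5 further gene lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.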

Results

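Total RNA of 6 samples of the budding yeast Saccharomyces cerevisiae was measured on Affymetrix expression arrays, 3 arrays of the wild type and 3 of a strain in which PMR1 is deleted. PMR1 encodes the Golgi calcium and manganese pump, a P-type ATPase that fills the secretory pathway with both ions. Cells of both strains grew to exponential phase in rich medium with 5 mM calcium chloride added, so the comparison asks how transcript levels differ between the deletion strain and the wild type under added calcium. The labels do not say whether the replicates were separate cultures, and the p-values measure only the spread between these samples, which may be technical. Over the 5498 probe sets that the annotation names for S. cerevisiae, the array medians lay between 10.34 and 10.39 on the log2 scale, and 1747 probe sets for the fission yeast Schizosaccharomyces pombe had medians of 3.22 to 3.28. Pearson's r across probe sets, which are not independent replicates, was 0.997 to 0.999 within groups and 0.988 to 0.990 between groups.

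The deleted gene was checked before any direction was drawn. PMR1 (YGL167C) had a level of 11.81 ± 0.021 (SD, n = 3) in the wild type and 3.13 ± 0.33 (SD, n = 3) in the deletion, where it was at the background of the arrays, so it was at least 186-fold lower (limma adjusted p = 3.43e-07). All 3 deletion values lay below all 3 wild-type values. The two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 allow. HUR1 (YGL168W), which overlaps PMR1 in the R64 gene table, fell by 3.03 on the log2 scale (SE 0.15, adjusted p = 5.07e-05), from 7.77 to 4.74. CUP2 (YGL166W), the adjacent gene for a copper-sensing transcription factor, rose by 0.64 (SE 0.045, adjusted p = 0.00017). Of the marker genes that the labels list as deleted in the background of both strains, URA3 and MET17 were at background in both groups, which gives no fold. URA3 was still lower past the threshold (limma adjusted p = 0.0254), so a small call appeared where the labels leave no transcript. Without wild-type replicate 3 or deletion replicates 1 or 2 its adjusted p was 0.0541 to 0.0712. LEU2 had levels of 5.55 and 5.32 (log2 change -0.23, adjusted p = 0.0349), and its adjusted p was 0.0555 to 0.0994 without wild-type replicates 1, 2 or 3 or deletion replicates 1 or 3. HIS3 had levels of 11.55 in the wild type and 11.57 in the deletion (adjusted p = 0.7). Where its probes lie relative to the deleted part is not in the tables used here, so HIS3 checks nothing.

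Loss of PMR1 was accompanied by many changes of modest size and by larger changes of few genes. The largest rise was that of RTA1, a membrane protein of the lipid-translocating exporter family, with a log2 change of 2.18 (SE 0.036, adjusted p = 3.43e-07). It was followed by YNR064C, an epoxide hydrolase gene, at 1.69 (SE 0.098), and by BNA2, the tryptophan dioxygenase at the start of NAD synthesis from tryptophan, at 1.57 (SE 0.12). YSR3, a phosphatase of sphingoid base phosphates, rose by 1.56 (SE 0.045, adjusted p = 5.6e-06), and PUG1, a transporter of protoporphyrin and heme, by 1.49 (SE 0.15). OSW2, a spore wall gene, rose by 1.42, YPT53, a Rab GTPase of endosomes, by 1.37, and MND1, a meiotic recombination gene, by 1.32. The other genes among the 15 largest rises were YPS3, PBI1, HES1, DIA1, GAP1, PBI2 and SRL3, between 1.08 for SRL3 and 1.25 for YPS3, and the adjusted p over all 15 was at most 0.000681.

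Genes that respond to iron supply were among the largest falls. LSO1, a small protein gene induced when iron is scarce, had a level of 7.03 in the wild type and was at background in the deletion, at least 2.75 lower on the log2 scale (adjusted p = 0.00035). FIT2 and FIT3, mannoproteins of the cell wall that retain iron bound to siderophores, fell by 2.70 (SE 0.18, adjusted p = 0.000149) and 2.68 (SE 0.18, adjusted p = 0.000161), and FIT1 fell by 1.62 (SE 0.25). RSB1, a transporter of sphingoid long-chain bases, fell by 2.21 (SE 0.27). HSP12 and HSP26, which encode small heat shock proteins, fell by 2.14 (SE 0.13) and 1.98 (SE 0.29), and HXT4, a hexose transporter, by 1.85 (SE 0.12). ARG1 and ARG3 of arginine synthesis fell by 1.63 (SE 0.12) and 1.62 (SE 0.17), and YKR075C, FMP23 and CIS1 fell by 1.81, 1.62 and 1.62. The adjusted p over these falls was at most 0.00427, the value of CIS1. Wild-type replicate 2 stood apart in part of this group: it had the highest wild-type value for 27 of the 42 probe sets that were at least 2-fold lower, and its median excess over the mean of the other two was 0.28. Without it FIT2 was at -2.47, FIT3 at -2.45, HSP26 at -1.60, RSB1 at -1.87 and CIS1 at -1.29.

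Over all genes, 963 probe sets were higher and 642 lower in the deletion by limma, together 29.2% of the 5498 tested, and they stand for 1603 genes. At least 2-fold, 22 were higher and 42 lower, and the median absolute log2 change of those past the threshold was 0.26. Without adjustment 2303 had p under 0.05. The 3 values of each group did not overlap for 2567 probe sets (46.7%, against 10% by chance), and this held for each gene named here as risen or fallen. Leaving out wild-type replicate 1 or deletion replicate 1 lowered the count of higher probe sets to 633 and 599, and leaving out deletion replicates 1 or 3 lowered the count of lower ones to 373 and 398. With all probe sets of the array in the test the counts were 548 and 325, control, unnamed and S. pombe probe sets included. With array weights the counts were 1434 and 1087.

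**Figure D1:**
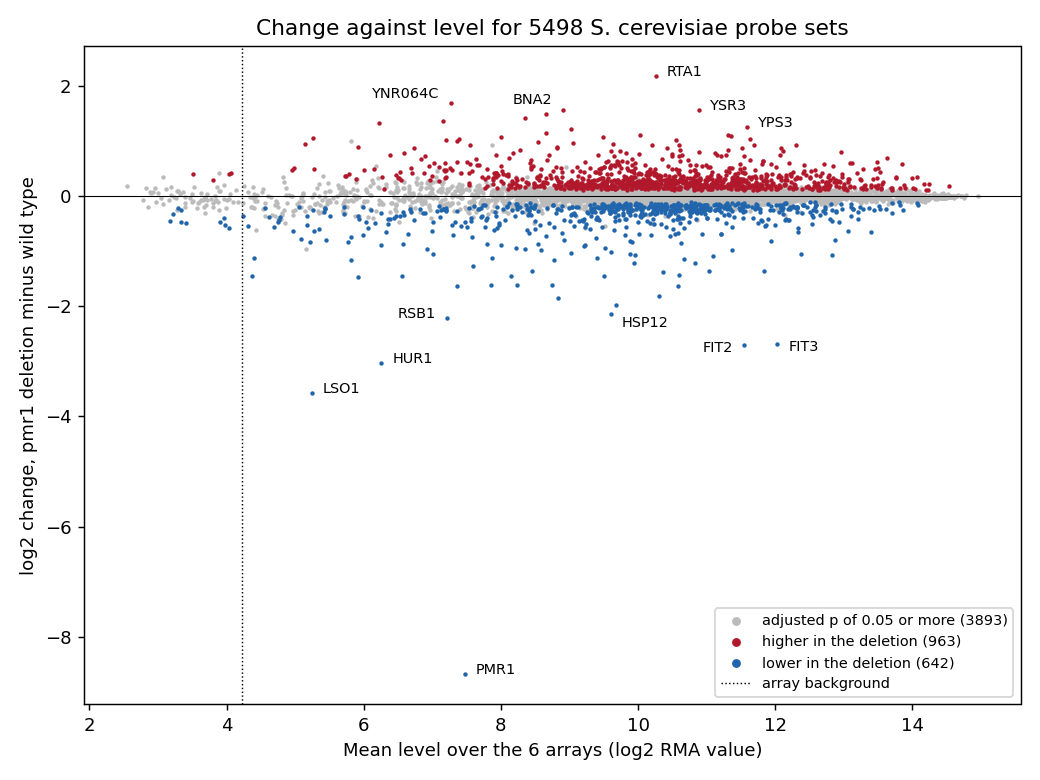
Log2 change (deletion minus wild type, y axis) against the mean log2 level over the 6 arrays (x axis) for each tested S. cerevisiae probe set, coloured by whether it was higher, lower or not past the threshold. The dotted line is the background of the mean levels, 4.23. PMR1 lies lowest at a fitted log2 change of -8.68, which is no bound, RTA1 highest at 2.18, and most of the probe sets past the threshold lie within 1 log2 unit of no change.

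Among genes of calcium signalling and of the cell wall, rises outnumbered falls. Of 19 measured targets of calcineurin and Crz1, the phosphatase and transcription factor that respond to cytosolic calcium, 16 rose and 0 fell, and 16 rose adjusted over the list alone. The median log2 change was 0.56 (camera adjusted p = 7.76e-12), with an adjusted p = 0.1 with an estimated correlation. RCN1 and RCN2, regulators of calcineurin, rose by 0.93 (SE 0.038, adjusted p = 2.59e-05) and 0.81 (SE 0.043, adjusted p = 6.01e-05). YPS1, an aspartic protease of the cell surface, rose by 0.92 (SE 0.046), and MEP1, an ammonium permease, by 0.84 (SE 0.041). As 15 of these targets also stand in other lists, the lists are not independent. The calcium homeostasis list had 7 higher and 1 lower of 17, and likewise 7 and 1 adjusted over the list alone (median 0.07, camera adjusted p = 0.019), with an adjusted p = 0.768 with an estimated correlation. Beside RCN1 and RCN2, the calmodulin-dependent kinase CMK2 rose by 0.75 (SE 0.055) and PMC1, the calcium pump of the vacuole, by 0.50 (SE 0.046, adjusted p = 0.00045). The call of this list ended without wild-type replicate 2 (adjusted p = 0.0612) and with array weights (0.071).

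Of 37 measured genes of the cell wall and the cell wall integrity pathway, 20 rose and 5 fell, and 22 and 5 did adjusted over the list alone. Their median log2 change was 0.22 (camera adjusted p = 0.000679), with an adjusted p = 0.325 with an estimated correlation. YPS3, a relative of YPS1, rose by 1.25 (SE 0.085), KDX1, a kinase-like paralog of the pathway's kinase SLT2, by 1.00 (SE 0.076, adjusted p = 0.000222), and SLT2 itself by 0.83 (SE 0.047, adjusted p = 8.18e-05). TIP1, a cell wall mannoprotein, fell by 1.05 (SE 0.09, adjusted p = 0.000336), SCW11, a glucanase of daughter-cell separation, by 0.43, and CWP1, another mannoprotein, by 0.42.

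**Figure D2:**
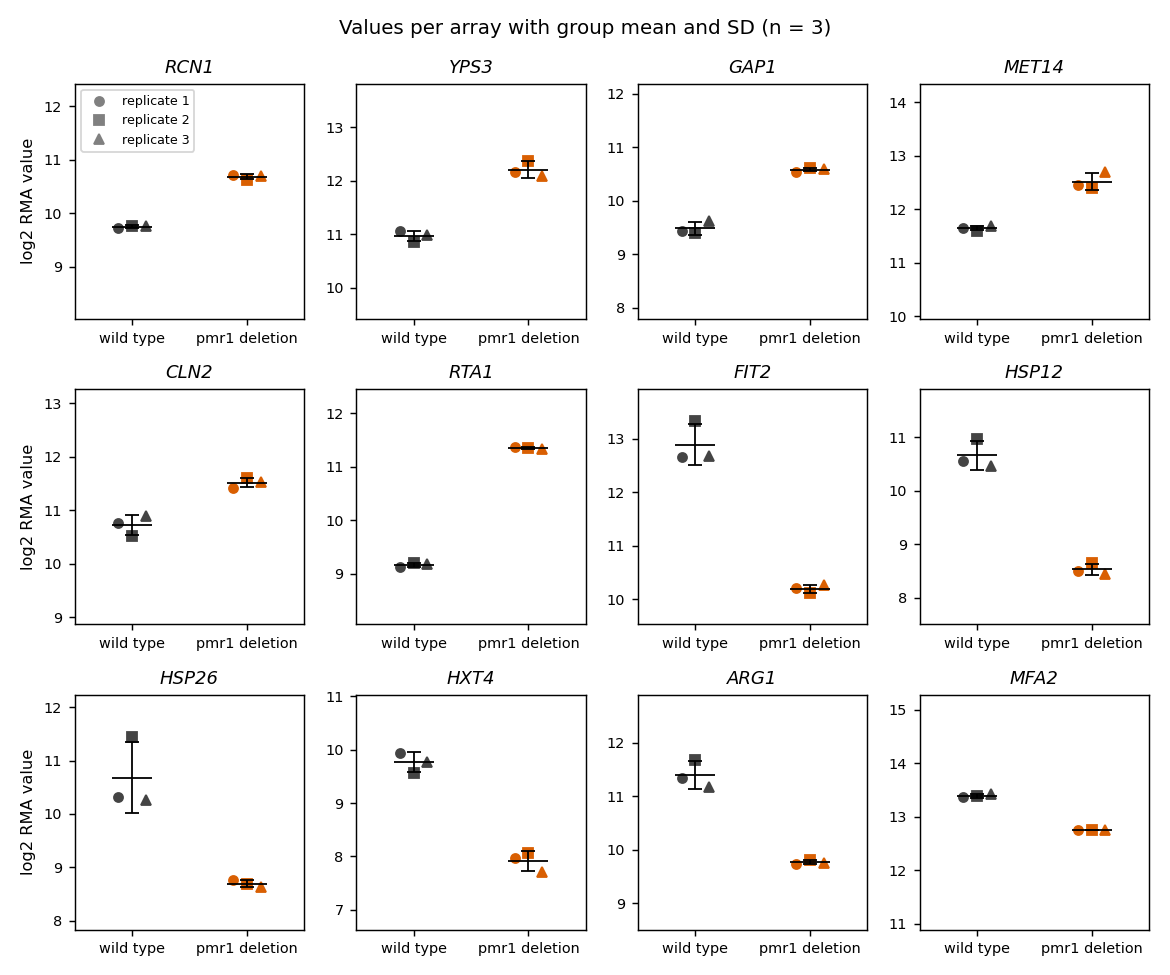
Log2 level (y axis) of 12 named genes on the 3 wild-type and 3 deletion arrays (x axis, a point per array with its shape for the replicate number), with the mean of each group as a horizontal line and its SD as the error bar. RCN1, YPS3, GAP1, MET14, CLN2 and RTA1 lie higher on all 3 deletion arrays, and FIT2, HSP12, HSP26, HXT4, ARG1 and MFA2 lie lower.

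Among nitrogen, sulfur and sterol genes, rises also outnumbered falls. Of 27 measured genes under nitrogen catabolite repression, the group that yeast silences on good nitrogen sources, 18 rose and 1 fell, and 18 and 2 did adjusted over the list alone. Their median log2 change was 0.31 (camera adjusted p = 1.04e-05), with an adjusted p = 0.1 with an estimated correlation. The general amino acid permease GAP1 rose by 1.10 (SE 0.06, adjusted p = 7.33e-05), the proline oxidase PUT1 by 0.88 (SE 0.039, adjusted p = 3.39e-05) and the ammonium permease MEP2 by 0.78 (SE 0.059). In sulfur and methionine metabolism 14 of 30 rose and 1 fell, and 16 and 1 did adjusted over the list alone (median 0.19, camera adjusted p = 0.000412), with an adjusted p = 0.229 with an estimated correlation. MET14, the kinase of sulfate activation, rose by 0.87 (SE 0.08), MHT1, a homocysteine methyltransferase, by 0.55, MET3, the sulfurylase of sulfate activation, by 0.51, and MET13, a methylenetetrahydrofolate reductase, by 0.43, while the S-adenosylmethionine permease SAM3 fell by 0.35 (adjusted p = 0.00289). In ergosterol synthesis 13 of 26 rose and 0 fell, and 17 and 1 did adjusted over the list alone (median 0.14, camera adjusted p = 0.000412), with an adjusted p = 0.501 with an estimated correlation. The sterol-responsive transcription factor UPC2 rose by 0.52 (SE 0.065), ERG26 by 0.45, the squalene synthase ERG9 by 0.35 and the farnesyl diphosphate synthase ERG20 by 0.33.

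Amino acid and phospholipid genes moved in both directions. Of 47 measured genes of amino acid synthesis under Gcn4, 9 rose and 12 fell, and 9 and 13 did adjusted over the list alone (camera adjusted p = 0.376). Besides ARG1 and ARG3, SNZ1, a gene of vitamin synthesis, fell by 0.89 (SE 0.14), while LYS9 of lysine synthesis rose by 0.48 (SE 0.035, adjusted p = 0.000185). Of 26 genes of inositol and phospholipid synthesis 7 rose and 2 fell, and 9 and 3 did adjusted over the list alone (camera adjusted p = 0.345). OPI3, a phospholipid methyltransferase, rose by 0.51 (SE 0.093), CKI1, the choline kinase, by 0.46 (SE 0.069), and INM1, an inositol monophosphatase, fell by 0.30 (SE 0.062), with a call that ended with all probe sets of the array in the test (adjusted p = 0.0505).

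Among genes of the iron regulon, falls outnumbered rises. Of 29 measured targets of the iron-responsive factors Aft1 and Aft2, 11 fell and 2 rose, and 11 and 3 did adjusted over the list alone. Their median log2 change was -0.15 (camera adjusted p = 0.00374), with an adjusted p = 0.768 with an estimated correlation, and fry's directional test gave an adjusted p of 0.0816. Besides FIT1, FIT2 and FIT3, the siderophore transporter ARN2 fell by 1.44 (adjusted p = 0.00551), and FRE5, a reductase gene, had a level of 5.10 in the wild type and was at background in the deletion, at least 0.82 lower (adjusted p = 0.00229). FRE4, another reductase gene, rose by 0.43 (adjusted p = 0.00564). LEU2, which the labels give as deleted in both strains, had levels of 5.55 and 5.32, above the array background. As the mean levels of FRE5 lie below these, its bound may not hold. The bounds of PMR1 and LSO1 rest on the same background and would be smaller with a floor at the level of LEU2. The level of HUR1 in the deletion, 4.74, also lies below those of LEU2. Wild-type replicate 2 was above the mean of the other two by 0.67 for FIT2, 0.69 for FIT3, 0.96 for FIT1, 0.91 for ARN2 and 0.72 for FRE5, and without it FIT1 was at -1.30 and ARN2 at -1.13. In the manganese and divalent metal list 1 of 15 rose and 2 fell, and 1 and 2 did adjusted over the list alone (camera adjusted p = 0.222). FET4, a low-affinity transporter of iron and other metals, fell by 0.70 (SE 0.054, adjusted p = 0.00024), the manganese transporter SMF1 fell by 0.25 (SE 0.043), and TRE2, which acts in the degradation of that transporter, rose by 0.29 (SE 0.045).

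In the zinc regulon 4 of 17 rose and 3 fell, and 5 and 3 did adjusted over the list alone (camera adjusted p = 0.848). The zinc transporter ZRT1 rose by 0.92 (SE 0.13) and the zinc-responsive factor ZAP1 by 0.65 (SE 0.034, adjusted p = 6.01e-05). VEL1 was lower (adjusted p = 0.0122), with a wild-type level of 4.23 at the edge of the background and a deletion level below it, which gives no fold. In the copper regulon 2 of 12 rose and 2 fell, and 3 and 2 did adjusted over the list alone (camera adjusted p = 0.778). Besides the rise of CUP2, the copper transporters CTR1 and CTR3 fell by 0.34 (SE 0.036) and 0.25 (SE 0.051), and the call of CTR3 ended with all probe sets of the array in the test (adjusted p = 0.0538). In the phosphate regulon 2 of 18 rose and 4 fell, and 3 and 4 did adjusted over the list alone (camera adjusted p = 0.222). The acid phosphatases PHO11 and PHO5 fell by 1.07 (SE 0.087) and 0.51 (SE 0.076), and PHM6 fell by 0.51 (SE 0.06). The probe set of PHO11 is of a kind that can also bind near-identical transcripts.

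General stress genes were split between strong falls and smaller rises. Of 34 measured targets of Msn2 and Msn4, 9 rose and 7 fell, and 9 and 9 did adjusted over the list alone (camera adjusted p = 0.616). Besides HSP12 and HSP26, DDR2 fell by 1.46 (SE 0.21, adjusted p = 0.00309) and the hexokinase HXK1 by 1.13 (SE 0.15, adjusted p = 0.0025), while TPS2 of trehalose synthesis rose by 0.56 (adjusted p = 0.000463) and the trehalase NTH1 by 0.43 (adjusted p = 0.00218). Wild-type replicate 2 exceeded the mean of the other two by 1.15 for HSP26, 0.79 for DDR2, 0.58 for HXK1 and 0.46 for HSP12, and without it DDR2 was at -1.20 and HXK1 at -0.93. In the oxidative stress list 5 of 25 rose and 2 fell, and 2 and 1 did adjusted over the list alone (camera adjusted p = 0.605). The peroxiredoxin TSA2 rose by 0.54 (SE 0.11) and ATR1, a multidrug transporter, fell by 0.57 (SE 0.074). In glycolysis and fermentation 2 of 26 rose and 5 fell, and 2 and 5 did adjusted over the list alone (camera adjusted p = 0.222). The falls were led by the hexose transporters HXT4 and HXT7, and HXT7 fell by 1.46 (SE 0.11, adjusted p = 0.000186) on a probe set of a kind that can bind near-identical transcripts. PYK2, a pyruvate kinase, rose by 0.52 (SE 0.048).

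Of 37 measured genes of the respiratory chain and ATP synthase 7 rose and 0 fell, and 3 and 0 did adjusted over the list alone (camera adjusted p = 0.0618). NDI1, the NADH dehydrogenase of the inner membrane, rose by 0.34 (SE 0.056), SDH4 by 0.25 (SE 0.036) and QCR2 by 0.23 (SE 0.038). In the citrate and glyoxylate cycles and gluconeogenesis 8 of 27 rose and 10 fell, and 10 and 11 did adjusted over the list alone (camera adjusted p = 0.655). LSC2, a subunit of succinyl-CoA ligase, rose by 0.43 (SE 0.032), CIT3, a citrate synthase, by 0.38 (SE 0.071), and the malate dehydrogenase MDH1 and the malate synthase MLS1 fell by 0.41 each (SE 0.055 and 0.078).

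Of the genes of the secretory pathway that passed the test, most rose. Of 25 measured genes of the unfolded protein response and folding in the ER, 7 rose and 0 fell, and 7 rose adjusted over the list alone (median 0.06, camera adjusted p = 0.0187), with an adjusted p = 0.768 with an estimated correlation. The disulfide isomerase EUG1 rose by 0.32 (SE 0.044), the prolyl isomerase FPR2 by 0.25 (SE 0.043) and the sulfhydryl oxidase ERV2 by 0.23 (SE 0.039). Without wild-type replicate 2 the adjusted p of this list was 0.0765. In glycosylation in the ER 4 of 34 rose and 0 fell, and 2 rose adjusted over the list alone (camera adjusted p = 0.369), with the mannosidase MNS1 at 0.26 (SE 0.052, adjusted p = 0.0108). In Golgi glycosylation 9 of 27 rose and 1 fell, and 10 and 1 did adjusted over the list alone (camera adjusted p = 0.0623). The mannosyltransferase genes KTR2, MNT4 and YUR1 rose by 1.03 (SE 0.044, adjusted p = 3.14e-05), 0.93 (SE 0.066) and 0.51 (SE 0.057), and OCH1, which starts the outer mannan chain, rose by 0.35 (SE 0.047).

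Of 31 measured genes of vesicle coats 8 rose and 0 fell, and 8 rose adjusted over the list alone (median 0.09, camera adjusted p = 0.00491), with an adjusted p = 0.768 with an estimated correlation. VPS17 and VPS35 of the retromer rose by 0.32 (SE 0.041) and 0.22 (SE 0.046), and SFB2 of the COPII coat by 0.23 (SE 0.039). The call of VPS35 ended with all probe sets of the array in the test (adjusted p = 0.0616). Among SNAREs, Rabs and tethers 9 of 39 rose and 3 fell, and 11 and 3 did adjusted over the list alone (camera adjusted p = 0.234). Besides YPT53, the endosomal SNARE PEP12 rose by 0.68 (SE 0.05, adjusted p = 0.000193). Of 20 genes of the vacuolar ATPase 1 rose, VMA1, at 0.12 (SE 0.037, adjusted p = 0.047), and 0 did adjusted over the list alone (camera adjusted p = 0.911). The adjusted p of VMA1 was 0.0993 to 0.136 without wild-type replicates 1 or 3 or any of the 3 deletion replicates. Of 27 genes of autophagy and vacuolar hydrolases 10 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.10, camera adjusted p = 0.019), with an adjusted p = 0.768 with an estimated correlation. The vacuolar mannosidase AMS1 rose by 0.96 (SE 0.16), the proteases PRB1 and APE1 by 0.86 (SE 0.087) and 0.75 (SE 0.094), and ATG19, the receptor that delivers aminopeptidase to the vacuole, by 0.42 (SE 0.056). The call of this list ended without wild-type replicate 1 and without deletion replicate 1, with an adjusted p of 0.0567 each.

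**Figure D3:**
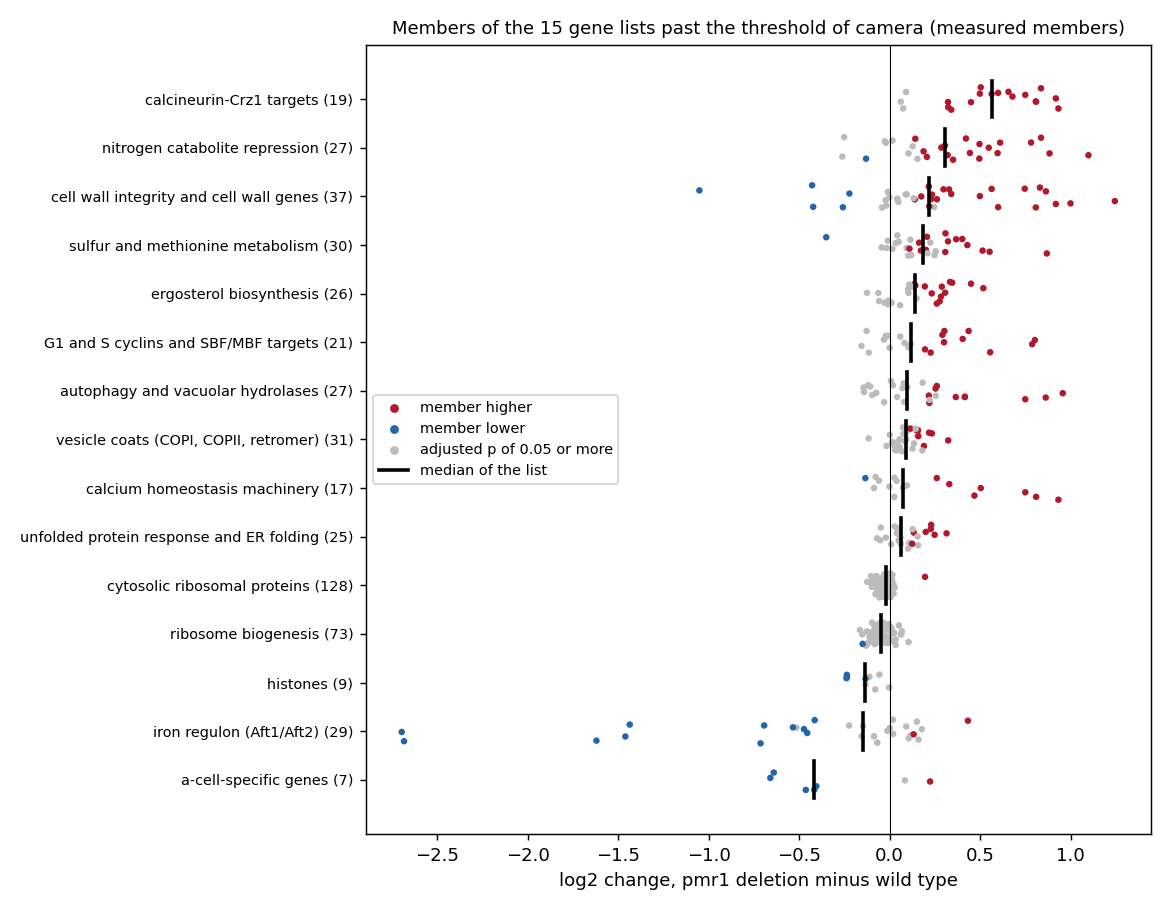
Log2 change (deletion minus wild type, x axis) of each measured member of the 15 gene lists past the threshold of camera (y axis, number of measured members in brackets), red where higher, blue where lower and grey where not past the threshold of limma, with the median of each list as a black bar. The calcineurin and Crz1 targets have a median of 0.56, the a-cell-specific genes a median of -0.42, and the ribosomal lists have medians of -0.02 and -0.05, close to 0.

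Among genes of G1 and S phase, rises outnumbered falls. Of 21 measured G1 and S cyclins and targets of their transcription factors 10 rose and 0 fell, and 11 and 2 did adjusted over the list alone (median 0.12, camera adjusted p = 0.0154), with an adjusted p = 0.768 with an estimated correlation. PCL1 rose by 0.80 (SE 0.08), CLN2 by 0.79 (SE 0.096), CLN1 by 0.56 (SE 0.059) and SWE1, a kinase that delays mitosis, by 0.44 (SE 0.066). The call of this list ended without wild-type replicate 2 (adjusted p = 0.0943) and with array weights (0.0535). In the M and M/G1 list 0 of 22 rose and 5 fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.205). DSE2, DSE1, SCW11 and CTS1, genes of daughter-cell separation, fell by 0.58 (SE 0.066), 0.57 (SE 0.047), 0.43 (SE 0.041) and 0.26 (SE 0.052). Of 9 histone genes 0 rose and 4 fell, and 6 fell adjusted over the list alone (median -0.13, camera adjusted p = 0.00374), with an adjusted p = 0.768 with an estimated correlation. HHF1 fell by 0.24 (SE 0.04, adjusted p = 0.00573) on a probe set of the kind that can bind near-identical transcripts, and the 2 probe sets of HTA2 gave -0.13 and -0.30, the former with an adjusted p of 0.0776 to 0.0998 without wild-type replicates 1 or 3 or deletion replicates 1 or 3. In the DNA damage and replication list 5 of 31 rose and 5 fell, and 5 and 5 did adjusted over the list alone (camera adjusted p = 0.51). The ribonucleotide reductase gene RNR2 rose by 0.30 (SE 0.03, adjusted p = 0.000676) and the helicase subunit MCM7 fell by 0.23 (SE 0.042).

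Few single ribosomal genes passed the test. Of 73 measured genes of ribosome biogenesis 0 rose and 1 fell, IMP4 at -0.15 (adjusted p = 0.047), and 0 passed adjusted over the list alone. The median was -0.05 (camera adjusted p = 0.00489), with an adjusted p = 0.768 with an estimated correlation, 0.385 by fry and 0.137 by camera without wild-type replicate 1. The adjusted p of IMP4 was 0.0671 to 0.135 without wild-type replicates 1 or 3 or any of the 3 deletion replicates. With the arrays shifted to a common median, quantile-normalized again or scaled by cyclic loess, 4, 9 and 7 genes of this list were lower and 0 higher. Of 128 cytosolic ribosomal protein genes 1 rose, RPL15B at 0.20 (adjusted p = 0.0376), 0 fell, and 0 passed adjusted over the list alone. The median was -0.02 (camera adjusted p = 0.00491), with an adjusted p = 0.768 with an estimated correlation and 0.113 by fry. RPL15B had an adjusted p of 0.0564 to 0.109 without wild-type replicate 1 or any of the 3 deletion replicates, and under the same 3 scalings 0 genes of this list were higher and 1, 2 and 1 were lower.

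Genes specific to the a mating type, the type of both strains by their labels, were mostly lower. Of 7 measured members 5 fell and 1 rose, and likewise 5 and 1 adjusted over the list alone (median -0.42, camera adjusted p = 0.00374), with an adjusted p = 0.325 with an estimated correlation. The a-factor genes MFA1 and MFA2 fell by 0.66 (SE 0.055, adjusted p = 0.000311) and 0.64 (SE 0.033, adjusted p = 5.84e-05), the alpha-factor receptor STE2 by 0.46 (SE 0.051), the agglutinin subunit AGA2 by 0.42 (SE 0.042) and the a-factor exporter STE6 by 0.41 (adjusted p = 0.00217). BAR1, the protease that degrades alpha factor, had levels of 12.01 and 12.10 (adjusted p = 0.313). The member that rose was ASG7, at 0.22 (adjusted p = 0.0289), and its adjusted p was 0.0501 to 0.0962 without wild-type replicates 1 or 3 or any of the 3 deletion replicates. Of 4 alpha-cell-specific genes, of which 1 was at background in both groups, 3 rose and 0 fell, and 3 rose adjusted over the list alone (camera adjusted p = 0.0818), with the a-factor receptor STE3 at 0.56 (SE 0.06, adjusted p = 0.000888). In the pheromone response 4 of 19 rose and 6 fell, and 4 and 6 did adjusted over the list alone (camera adjusted p = 0.12). KAR5 and SST2 fell by 0.49 (SE 0.05) and 0.42 (SE 0.035), and MSB2 rose by 0.36 (SE 0.06). In the sporulation list 3 of 14 rose and 2 fell, and 4 and 2 did adjusted over the list alone (camera adjusted p = 0.848). HOP1, DMC1 and DIT1 rose by 0.72 (SE 0.07), 0.47 (SE 0.047) and 0.43 (SE 0.091).

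In all, 15 of the 35 lists passed camera, 10 upwards and 5 downwards, and fry's directional test passed 16. With the correlation estimated for each list camera passed 0, with a smallest adjusted p = 0.1, and 4 to 13 lists passed camera with its preset correlation in the 9 other splits of the 6 arrays. Each of those splits has both strains on both sides and keeps part of the strain difference, so these counts are no chance level. The zinc and copper lists had a median and a mean above 0 and a downward camera direction. The citrate and Gcn4 lists had a median above 0 (0.014 and 0.001) and a mean below 0 (-0.028 and -0.081), the sporulation list had a median of -0.022 and a mean of 0.076, and fry gave the zinc, copper, citrate and DNA damage lists the opposite direction to camera. The medians of the zinc, copper, citrate, Gcn4, sporulation, vacuolar ATPase and ER glycosylation lists changed sign under at least 1 other scaling of the arrays.

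No chromosome was shifted by anything near the log2 rise of 1 that an extra copy would give. The largest difference of a chromosome's median from the rest was 0.022 on the log2 scale, on chromosome I (pooled SD 0.0056), with a smallest exact permutation adjusted p of 0.32 over the 16 chromosomes. With 3 arrays against 3 the exact permutation p cannot go below 0.1.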

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

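The tests here, except that of a change spreading along the chromosome, were chosen only after the result was seen. Signals also appeared in probe sets that the comparison does not use. A reporter control probe set of the array had a level of 3.14 ± 0.057 (SD, n = 3) in the wild type, at background, and 14.24 ± 0.039 (SD, n = 3) in the deletion, a fitted log2 change of 11.10 (limma adjusted p = 8.14e-10) and at least 1023-fold higher. Of the 46 other reporter probe sets 1 passed the threshold, and the largest absolute log2 change among them was 0.40. Per the labels a kan marker replaces PMR1 in the deletion, and whether this reporter probe set detects the marker is not given in the tables used here. Of all 213 control probe sets 3 were lower past the threshold, by 0.44, 0.41 and 0.38, which is more than the 0.26 median absolute change of the genes called. They detect Bacillus subtilis transcripts added as controls, and 40 of the 42 probe sets for these had a log2 change below 0 (median -0.24), as did 27 of the 27 for the labelled hybridisation controls (median -0.16), although the array means of the latter overlapped between the groups (10.974 to 11.237 in the wild type, 10.913 to 10.998 in the deletion). Several probe sets measure each control, so they are not independent. A technical difference between the groups of arrays stays open here, and its bearing on the small changes of genes was not tested. Among 3470 unnamed probe sets 52 were higher and 22 lower, 5 of them at least 2-fold higher, with a largest rise of 1.60 and a largest fall of -1.11. Among 1747 probe sets for S. pombe 8 were higher and 5 lower, 0.74% of them, with a largest absolute log2 change of 0.44.

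The 42 probe sets that were at least 2-fold lower in the deletion include genes of iron uptake, stress and hexose transport beside others, and a difference between cultures or arrays could produce such a group. Wild-type replicate 2 alone does not account for it, since without that array the median log2 change of the 42 went only from -1.41 to -1.23. The array does add to the size: GTO3, SNO1, HXK1, TIP1 and YMR317W were then less than 2-fold lower, at -0.83 to -0.99. Without it 42 of the 42 were still lower past the threshold. Leaving out a high array also narrows the wild-type spread, so that count alone decides little. Wild-type cultures closer to glucose exhaustion would have more respiratory transcripts, and the median log2 change of the respiratory chain list in the deletion was 0.057 (95% bootstrap interval over genes 0.037 to 0.087), not below 0. In the citrate, glyoxylate and gluconeogenesis list 10 members, MLS1 and MDH1 among them, fell and 8 rose. With a median of 0.014 (camera adjusted p = 0.655) that list showed no net shift. HXT7, HXK1, HSP12 and HSP26 were lower too, but they are among the 42 and so belong to the group to be explained. The respiratory list did not fall and the citrate list moved both ways, so together they do not decide, and glucose exhaustion stays open. Also open, and untested here, are the loss of PMR1 itself and other differences in the state of the cultures at harvest.

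The a-cell-specific genes were lower and STE3 higher in the deletion, which might point to a change in the cells of the culture. Fewer a cells in the deletion cultures would lower all a-cell-specific transcripts alike, but BAR1 had a log2 change of 0.085 (SE 0.058) against the list median of -0.42. BAR1 was picked from the same 7 genes after its value was seen. It shows that the members did not move alike, and a part played by fewer a cells stays open. Diploid cells would lower haploid-specific genes by a similar amount, but the median log2 change of 10 such genes was 0.028 (95% bootstrap interval -0.13 to 0.17). They moved apart: FUS3 and NEJ1 rose by 0.29 and 0.22, and FAR1 and GPA1 fell by 0.25 and 0.21. In the sporulation list of diploid-specific genes 3 of 14 rose, HOP1 and DMC1 among them, and 2 fell, so that list does not decide. A regulatory effect of the deletion on STE3 and part of the a-cell-specific genes stays open as a hypothesis and was not tested.

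HUR1 was lower and CUP2 higher beside the deleted gene. Part of HUR1 may have been removed with PMR1, since 54.4% of the HUR1 gene overlaps PMR1 in the gene table. The ends of the deleted part and the place of the HUR1 probes within the gene are not in the tables used here. A change spreading along the chromosome from the replaced gene is argued against by the 10 nearest other genes, whose median absolute log2 change of 0.062 lay at the 16.4th percentile of 5300 windows of 10 genes, although 3 of them passed the threshold. An effect limited to CUP2 itself, from the marker or from the lost pump, stays open.

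The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 963 higher and 642 lower probe sets and the highest count in any other split was 0, at least 2-fold it gave 22 and 42 against 0, and it gave 15 gene lists against 13, so in each case 1 split, the real split, had a count as large. Each other split has both strains on both sides, so a strain difference widens the spread within its groups. Counts of 0 there are no chance level.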

How the results depend on the processing

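The added background floor, the 5 further gene lists and the values of their fallen members without wild-type replicate 2 were chosen only after the data were seen, and all other alternatives were planned. Over all alternatives 0 of the 2139 values of 143 named genes past the threshold reversed, 1970 kept their side of it and 169 lost the call, from 30 genes, 109 of them when an array was left out. With all probe sets of the array tested, 548 were higher and 325 lower, control, unnamed and S. pombe probe sets included. Of these 873 calls 781 were shared with the 1605 of the main setting. More probe sets then enter the adjustment and the estimate of the spread, and the cause of the lower counts was not tested. Array weights gave 1434 higher and 1087 lower, and the cause was not tested. Camera with an estimated correlation passed 0 lists (15 in the main setting). For nitrogen catabolite repression the estimated correlation was 0.003, under the preset 0.01, yet the camera adjusted p went from 1.04e-05 to 0.1. A higher correlation thus did not raise that value, so correlation between genes alone does not account for the 0 lists. The cause was not tested further. Without each array in turn, higher probe sets ranged from 599 to 1041, lower from 373 to 629, those at least 2-fold higher from 20 to 25 and lower from 36 to 47, the fitted log2 change of PMR1, which is no bound, from -8.84 to -8.51, and the lists from 12 to 17. The difference of the median of chromosome I, the largest in the main setting, ranged from 0.0158 to 0.026 without each array. With the replicate block 805 were higher and 570 lower, 22 and 42 at least 2-fold, PMR1 was at a fitted -8.68 (adjusted p = 0.000244), and 15 lists passed. Correlations of the deviations of same-numbered samples were -0.138, 0 and 0.081, so no large shared deviation by replicate number was seen. Whether same-numbered samples were handled together is not known. All other alternatives kept each count within 1.5 times of its main value, with 53.1% to 64.4% of calls higher over all alternatives, against 60% in the main setting. The signal over background limits the bounds of PMR1, LSO1 and FRE5.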

Other observations

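The 5 gene groups described here, and their tests, were all chosen only after the values were seen, so their p-values describe these samples and test nothing independently. Part of the genes that take up and phosphorylate hexoses fell: of 21 measured hexose transporters, kinases and regulators 7 fell, 1 rose and 13 did not pass (median -0.06, camera adjusted p = 0.0125), with an adjusted p = 0.285 with an estimated correlation. Besides HXT4 and HXT7, MTH1, a repressor of hexose transporter genes, fell by 1.36 (limma adjusted p = 5.07e-05) and HXK1 by 1.13. The cell wall mannoproteins of the TIR and DAN family, which yeast makes in the cold and without oxygen, fell in 5 of 7 cases and rose in 0 (camera adjusted p = 0.00146), with an adjusted p = 0.335 with an estimated correlation. TIR3 fell by 1.21, TIP1 by 1.05, TIR1 by 0.98, TIR4 by 0.87 and TIR2 by 0.34. Wild-type replicate 2 had the highest wild-type value for each of these 5 genes, by a median of 0.29 over the mean of the other two, and without it their median log2 change went from -0.98 to -0.81, with TIR3 at -1.12, TIP1 at -0.96, TIR1 at -0.81 and TIR4 at -0.67. It was the highest for 3 of the 7 fallen hexose genes, whose median went from -1.13 to -0.93.

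Targets of the drug resistance factors Pdr1 and Pdr3 moved apart. Of 16 measured members 9 fell and 3 rose (camera adjusted p = 0.0125), with an adjusted p = 0.559 with an estimated correlation. RSB1 fell by 2.21 and the ABC transporters PDR15 and SNQ2 by 0.94 and 0.57. RTA1, the largest rise among the tested S. cerevisiae probe sets, stood at 2.18. Wild-type replicate 2 had the highest wild-type value for 9 of the 9 fallen members, by a median of 0.30 over the mean of the other two, and without it their median log2 change went from -0.54 to -0.43, with RSB1 at -1.87, PDR15 at -0.73 and SNQ2 at -0.47. In both lists, and among the hexose genes, each fallen member was still lower past the threshold without it. Of 11 genes for NAD synthesis from tryptophan 8 rose and 1 fell (camera adjusted p = 0.00146), with an adjusted p = 0.257 with an estimated correlation. BNA2 rose by 1.57, BNA1 by 0.52, NPT1 by 0.42 and BNA3 by 0.37. Of 22 genes of meiotic recombination and the spore wall 7 rose and 3 fell (camera adjusted p = 0.302), with OSW2 at 1.42 and MND1 at 1.32 among the risen.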
